A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

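Gene expression was followed during sporulation of the budding yeast Saccharomyces cerevisiae on 7 spotted arrays with 2 channels each. Total RNA labelled as time zero was in channel 1 of every array, and channel 2 held RNA from 0, 0.5, 2, 5, 7, 9 or 11 h. Each time point had 1 array and no replicate, so the number of arrays limits the precision. The first array, time zero against time zero, measured the technical spread of 1 array and not the spread between cultures.

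The deposited values were log ratios of the 2 channels, given with 3 decimals for 6384 probes. ScanAlyze of unknown version was named as the scanning software, and the data as converted from another format, per the labels. Background correction, spot filters and normalization are not given in the sources used here. Array means lay near 0, from -0.00935 to 0.0111, and array medians were 0, 0.0325, -0.018, -0.049, -0.107, -0.072 and -0.128 from 0 to 11 h. The log base is not stated. A largest value of 6.06 exceeds the 4.82 that a log10 ratio of 16-bit intensities can reach. The deposited ratios, whose processing by the authors is otherwise unstated, were therefore taken as log2 values, which is likely, while a natural log was not excluded and would make every fold change larger. The direction, time point over time zero, was likewise taken as likely from the order of the channels, since no dye is given. Between 6151 and 6362 probes had a value on an array.

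Gene names came from the platform annotation, which lists 5516 of the probes with 1 gene symbol, none with several and leaves 868 unnamed, and symbols were updated through gene identifiers to the R64 reference. Names were not read directly by row number. Read that way, repeat probes of one gene had a median correlation over the later arrays of 0.0519 (43 pairs), and ribosomal protein probes had a median of -0.009 at 7 h. This was noticed after the values of key genes had been seen under that naming. Values on the time zero array repeated along the rows at a lag of 24 (r = 0.475, the highest of lags 2 to 100). The annotation was therefore taken to be numbered by print tip (4 tips of 1596 spots) and the value rows to run in plate order, with each 24 rows divided over the 4 tips. Rows were converted accordingly. After conversion the repeat probes had a median correlation of 0.842 (47 pairs), and the other 23 tip orders reached at most 0.793. The SD of ribosomal protein probes at 7 h was 0.621, against at least 1.04 for the other tip orders and 1.19 by row number. Further checks, made after the conversion was chosen, covered all 25 namings. The mean correlation within 22 gene lists other than ribosomal proteins was 0.428, against at most 0.206 for the other tip orders and 0.00704 by row number, and 15 of the 22 lists had their highest correlation under the conversion. A check on 2 pairs of genes named as A and B copies did not favour it (median r 0.0122, against up to 0.827 for another order). The conversion is an inference from the data, chosen after seeing them, and no source used here states the layout. Every gene name and gene list result rests on it, and coherence of gene lists is not independent evidence for their direction.

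Probes of a gene were averaged (45 genes had several), giving 5470 genes, of which 5029 had a value on all 7 arrays. Genes at or above 1 or at or below -1 on the log2 scale were counted at each time, with no pseudocount and no test, beside the same count on the time zero array. A trend over time was tested with limma 3.58.1 in R 4.3.3, as the moderated F-test of a natural spline of time with 3 degrees of freedom over the 7 arrays. This left 3 residual degrees of freedom, with 2.82 prior degrees of freedom, and the Benjamini-Hochberg adjusted p had to be under 0.05. The direction was the sign of the fitted change from 0 h at the sampled time where it was largest. Where the 0 h array was left out, the change was counted from 0.5 h. On simulated data for the same 5029 genes, changes followed smooth sigmoid or bell curves in time, with no step by 0.5 h. The trend test recovered 3 of 67 genes with a change of 1 on the log2 scale and 51 of 67 with a change of 2. It recovered 62 of 66 with a change of 3, and called 7 of 4829 unchanged genes. These shares do not cover genes that moved by 0.5 h. The simulated noise was independent between genes and arrays. The 7 calls therefore set no bound on false calls where many genes deviate together on an array.

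The 23 gene lists were fixed before the data were examined. The median of each list was ranked among 10000 random lists of equal size, and fry in limma tested the fitted change from 0 h to 2, 5 and 11 h, adjusted over all 69 tests. In 50 simulated data sets without change, with noise independent between genes, 4.52% of fry tests had an unadjusted p under 0.05. This share does not cover lists whose members deviate together. The sporulation lists hold genes known from sporulation time courses, this one possibly among them, so their counts are not independent evidence of direction. Genes named in the text were the 4 highest and 4 lowest at each later time among genes with a value on all 7 arrays and under 2-fold on the time zero array, 27 key genes, and per list the 2 members farthest from 0 at the time where the list median was farthest. This rule and the tests were set before the data were examined. Alternatives were median centring, subtraction of the time zero array (for trends and fry only together with a curve held at 0 at 0 h), quantile normalization, other curves, a robust prior, other filters and thresholds, other handling of repeat probes and leaving out each array. Naming by row number, centring per print tip, a test of lists in either direction and a simpler curve on 6 arrays were added after seeing the data. Summaries were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.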

Results

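Transcript levels of 5029 yeast genes were followed through 11 h of sporulation, the starvation response in which a diploid cell passes through meiosis and packages the products into spores. Each array set RNA from 1 time point against RNA from time zero, and values are log2 ratios of time point over time zero, a direction and log base that are likely but not stated. No time point was replicated. Gene names rest on an inferred conversion of array rows, chosen after the data had been seen because naming by row number gave incoherent genes. By row number the medians of 22 of 23 gene lists moved, most to near 0, and 11 changed sign.

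On the time zero against time zero array, genes scattered with an SD of 0.24, and the central 95% lay between -0.43 and 0.48. The central 99% lay between -0.56 and 0.65. Part of this scatter followed the inferred print tips, whose medians on this array ran from -0.126 to 0.143. With centring per print tip the SD was 0.20. Only 2 genes reached 2-fold higher there and 0 reached 2-fold lower. This background covers 1 array and not differences between cultures.

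The first comparison asked which genes stood apart from time zero at each time, and ranks are among genes with a value on all 7 arrays. At 0.5 h the highest genes were IME2 (4.75), a protein kinase that promotes meiosis, DMC1 (4.58), the meiotic recombinase, and the nitrogen permeases DAL5 (4.30) and MEP2 (4.05). The lowest were UTP13 (-4.11), PWP1 (-3.93), LTV1 (-3.76) and NOC2 (-3.75), all with roles in ribosome assembly. At 2 h MEI5 (4.58), LEU1 (4.22), MEP2 (4.18) and DMC1 (4.13) were highest. NCW2 (-3.55), BTN2 (-3.15), SPI1 (-3.04) and ZPR1 (-2.98) were lowest.

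At 5 h RNP1 (5.53), SPS4 (5.24), SLZ1 (5.13) and MEI5 (5.02) led, and NCW2 (-3.89), the glycolytic enzyme gene GPM1 (-3.82), YOR385W (-3.50) and SPI1 (-3.38) were lowest. At 7 h MIP6 (5.74), SSP1 (5.46), OSW1 (5.35) and LOH1 (5.34) were highest and TKL1 (-4.01), GPM1 (-3.96), NCW2 (-3.85) and HSP104 (-3.67) lowest. At 9 h the highest genes were MIP6 (5.03), the septin gene SPR3 (4.96), SSP1 (4.90) and AMA1 (4.79), a meiosis-specific activator of the anaphase-promoting complex. OLE1 (-3.66), HSP104 (-3.61), GPM1 (-3.57) and SCW10 (-3.37) were lowest at 9 h. At 11 h MIP6 (6.06), YEL023C (6.02), SPR28 (5.98) and PES4 (5.83) were highest, and OLE1 (-4.20), PRY2 (-3.71), CRH1 (-3.69) and BTN2 (-3.64) lowest.

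Genes at least 2-fold higher numbered 429 at 0.5 h, 393 at 2 h, 565 at 5 h, 782 at 7 h, 635 at 9 h and 635 at 11 h. Those at least 2-fold lower numbered 523, 394, 503, 868, 694 and 601 at the same times. Each count stood far above the 2 higher and 0 lower genes of the time zero array, and none of these counts has a replicate check. The median of all genes lay at -0.11 at 7 h, -0.12 at 9 h and -0.15 at 11 h, so late values relative to the median gene are higher by those amounts.

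**Figure D1:**
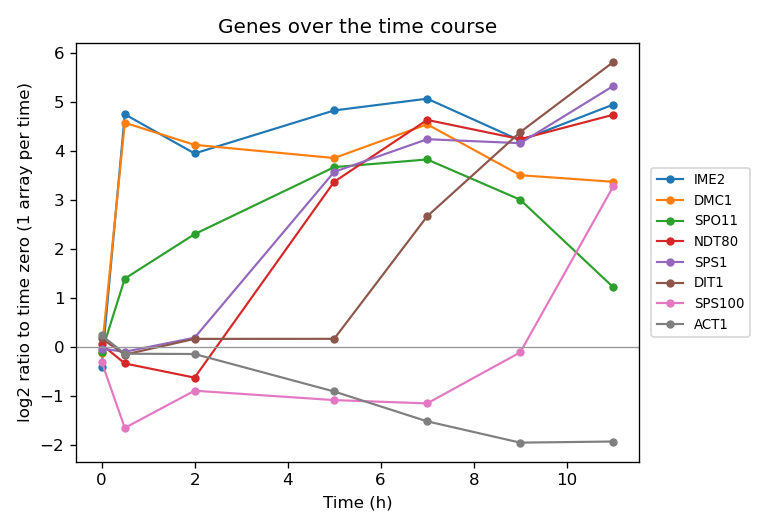
The log2 ratio to time zero (vertical axis) of 8 genes is plotted against time in hours, 1 array per point and no error bars because no time was replicated. IME2 and DMC1 lie above 4.5 at 0.5 h, NDT80 and SPS1 are near or below 0.2 until 2 h and above 3.3 from 5 h, and DIT1 and SPS100 reach 5.82 and 3.28 at 11 h.

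The second comparison asked which genes followed a smooth trend over the 7 times. Changes given with an SE are read off the fitted curve from 0 h and can differ from the measured ones. Each SE and adjusted p rests on the scatter of single arrays about that curve. Neither measures a spread between cultures or replicate arrays, since no time was replicated. NDT80, the transcription factor that switches on middle sporulation genes, rose (fitted change at 9 h 5.17 ± 0.50, SE; limma adjusted p = 0.0116). DIT1, needed for the dityrosine layer of the spore wall, rose by 5.77 ± 0.53 at 11 h (adjusted p = 0.0109), and MIP6 by 6.76 ± 0.53 at 9 h (adjusted p = 0.0109). SPO11, which makes the DNA breaks that start recombination, rose by 3.55 ± 0.43 at 5 h (adjusted p = 0.0156). As measured, MIP6 stood at -0.595 at 0 h and 5.03 at 9 h, and SPO11 at -0.112 at 0 h and 3.67 at 5 h. The actin gene ACT1 fell (fitted change at 11 h -2.07 ± 0.28, adjusted p = 0.0134), as did the cell wall genes CRH1 (-3.52 ± 0.33 at 11 h) and SCW10 (-3.04 ± 0.39 at 7 h).

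In all, 393 genes rose and 307 fell. On the fitted curve, the largest change was at 9 h for 151 of the rising genes and at 11 h for 100. Of those 151 genes, NDT80, MIP6 and CDC20 among them, 78 measured lower at 9 h than at both 7 and 11 h, so the curve's peak is not a measured one. For the falling genes it was at 11 h for 119 and at 7 h for 99. IME2 (adjusted p = 0.308), DMC1 (0.463) and LEU1 (0.21) did not pass although each lay above 3.3 at every later time. Each had risen by 0.5 h, a step that the curve follows poorly. The SE of their fitted change at 5 h was 1.56, 1.48 and 1.10, against 0.43 for SPO11. Not passing is therefore no evidence that a gene or list that moved by 0.5 h stayed unchanged. HOP1, CLB1, SMK1, HSP26 and NOP1 lacked a value on at least 1 array and were not tested.

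The number of trend calls changed strongly with the array left out, where each fit also had 2 residual degrees of freedom in place of 3. Without the 2 h array, and likewise without the 5 h array, limma called 0 genes, with 1195 and 1270 genes at an unadjusted p under 0.05. Without the 7, 9 or 11 h array 40, 99 or 75 genes rose and 3, 10 or 6 fell. Without the 0.5 h array 703 rose and 660 fell. With the 0 h array left out 848 rose and 914 fell, but counted from 0.5 h and not from time zero. Quantile normalization left 125 rising and 53 falling genes.

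Lists of genes fixed in advance were compared next. Among 21 genes of meiotic recombination and synapsis, the median stood at 1.40 at 0.5 h, 2.37 at 2 h, 3.67 at 5 h, 3.83 at 7 h, 3.19 at 9 h and 2.32 at 11 h. It exceeded all random lists of equal size at each of these times. Ranks were also extreme on the time zero array (percentile 0.67 for this list, 100 for ribosomal proteins). A rank alone therefore does not show a change. Of the 21 genes 13 rose and 0 fell, or 17 and 0 adjusted over the list alone. MEI5, a partner of DMC1, rose (5.38 ± 0.73 at 5 h), as did ZIP1 of the synaptonemal complex (3.94 ± 0.64 at 5 h). RED1 had 4.92 at 7 h but did not pass (adjusted p = 0.0675). HOP1 measured 3.47 at 0.5 h and 2.97 at 11 h. Among 14 regulators of meiosis 1 rose, NDT80, and likewise 1 adjusted over the list alone. The median of these regulators was highest at 9 h (0.84). IME1, the master inducer, measured 0.79 at 5 h and -1.19 at 11 h (adjusted p = 0.0593), UME6 1.16 at 7 h and RME1 1.43 at 11 h, and none of these passed.

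The list of middle genes, which build the prospore membrane and septins, stayed near 0 at 0.5 h (median 0.08) and 2 h (0.18). It stood at 3.56 at 5 h, 4.41 at 7 h, 4.003 at 9 h and 4.88 at 11 h. Of 22 members 20 rose and 0 fell, or 21 and 0 adjusted over the list alone. On the fitted curve SPR28 rose by 5.84 ± 0.55 at 9 h, SPS4 by 5.54 ± 1.22 at 11 h and SPS1 by 5.26 ± 0.65 at 11 h. The measured values at these times were 4.576, 5.635 and 5.332. SMK1 measured 1.49 at 9 h.

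Genes of the meiotic divisions, cyclins and the anaphase-promoting complex had a median of 0.38 at 2 h, 1.65 at 5 h and 3.03 at 7 h. Of 22 members 17 rose and 0 fell, or 18 and 0 adjusted over the list alone. CDC20 rose by 4.28 ± 0.46 and the polo kinase gene CDC5 by 4.23 ± 0.56, both at 9 h, and CLB6 by 3.85 ± 0.88 at 11 h. CLB1 measured 4.49 at 11 h. Spore wall and late genes had a median of -0.08 at 2 h, 2.06 at 5 h, 3.37 at 7 h and 3.88 at 9 h, and 13 of 15 rose and 0 fell, with equal counts adjusted over the list alone. On the fitted curve GAS4 rose by 5.66 ± 0.55 at 9 h (measured 4.524) and DIT2 by 3.57 ± 0.53 at 11 h (measured 3.685). SPS100 was at -0.11 at 9 h and 3.28 at 11 h, and rose by 3.99 ± 0.70.

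**Figure D2:**
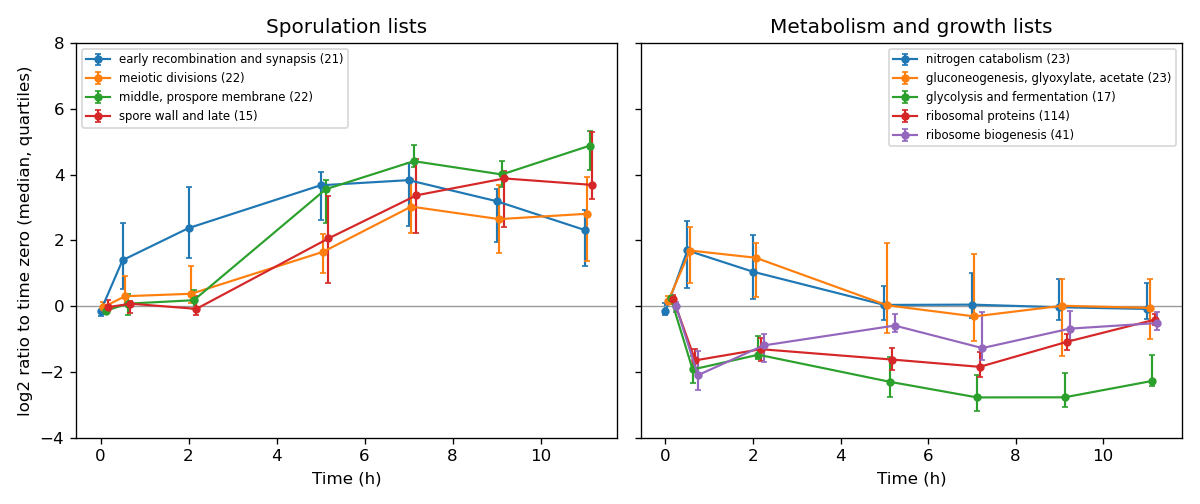
Medians of gene lists (points) with lower and upper quartiles of their members (bars) are plotted as log2 ratios to time zero against time in hours, with lists shifted slightly sideways and member counts in brackets. Early recombination genes stand at 1.40 at 0.5 h while middle genes stand at 0.08, and ribosomal proteins return from -1.85 at 7 h to -0.41 at 11 h.

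DNA replication genes had a median of 1.18 at 2 h, 1.06 at 5 h and -0.18 at 11 h. Of 27 members 8 rose and 2 fell, or 12 and 3 adjusted over the list alone. POL30, the replication clamp, rose by 2.41 ± 0.31 at 2 h, and RFA1 measured 2.58 at 2 h without passing. The 8 core histone genes had a median of -1.15 at 0.5 h, 0.59 at 2 h and -0.70 at 11 h, and 0 rose and 0 fell, also adjusted over the list alone. HTA1 went from -1.52 at 0.5 h to 0.32 at 2 h and HTB1 from -1.28 to 0.70.

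Nutrient genes stood highest at the first time. At 0.5 h the median was 1.69 for nitrogen catabolism (23 genes), 1.69 for gluconeogenesis, the glyoxylate cycle and acetate use (23), 1.91 for fatty acid oxidation (13), 1.26 for amino acid synthesis (42) and 0.74 for the TCA cycle (14). At 11 h these medians were -0.09, -0.06, 0.86, 0.13 and -0.12. The trend test called 0 rising and 1 falling for nitrogen catabolism, 1 and 6 for gluconeogenesis, 0 and 1 for fatty acid oxidation, 0 and 2 for amino acid synthesis and 2 and 3 for the TCA cycle. Adjusted over the list alone the counts were 0 and 0, 1 and 7, 0 and 1, 0 and 0, and 4 and 4. At 0.5 h CAT2 measured 3.54, YAT2 3.25, CTA1 3.81, FOX2 2.69, MET17 3.75 and ACO1 2.55. ACS1 measured 2.74 and ICL1 2.24 at that time, and SDH2 1.47. PCK1, of gluconeogenesis, measured -1.03 at 0.5 h and fell by 2.92 on the log2 scale at 5 h (SE 0.43, adjusted p = 0.0354).

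Glycolysis and fermentation genes (17) had medians of -1.93 at 0.5 h, -2.78 at 7 h and -2.28 at 11 h, below all random lists. Their median on the time zero array, 0.25, also had an extreme rank, at percentile 99.95. The trend test called 0 rising and 2 falling, also adjusted over the list alone. GPM1 measured -3.96, PGK1 -3.53 and CDC19 -2.26 at 7 h, none of which passed. Respiratory chain genes (28) had a median of -0.73 at 11 h, with 3 rising and 1 falling, or 4 and 1 adjusted over the list alone. ATP2 fell (-2.84 ± 0.43 at 11 h), while ATP1 measured -2.07 at 11 h without passing.

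Ribosomal protein genes (114) had medians of -1.65 at 0.5 h, -1.85 at 7 h and -0.41 at 11 h. At 7 h 101 of them were at least 2-fold lower. The naming was chosen partly on the scatter of these probes at 7 h, so this count is not independent of that choice. The trend test called 0 rising and 1 falling, and 0 and 0 adjusted over the list alone. RPS3 measured -2.81, RPS1A -2.77 and RPL3 -2.02 at 7 h. Ribosome biogenesis genes (41) were lowest at 0.5 h (median -2.10, 35 at least 2-fold lower), at -0.52 by 11 h, and 0 rose and 0 fell, also adjusted over the list alone. ROK1 measured -3.63 at 0.5 h. NOP1 measured 0.11 at 0.5 h and -0.83 at 9 h. Mitochondrial ribosome genes (48) had a median of -0.60 at 0.5 h, and 6 rose and 0 fell, with equal counts adjusted over the list alone. On the fitted curve MRPS17 rose by 4.05 ± 0.39 at 9 h, where it measured 3.133, from -0.162 at 0 h. MRPL24 measured 1.05 at 7 h without passing.

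General stress and storage carbohydrate genes (25) had medians of 0.03 at 0.5 h, -0.57 at 2 h and -1.28 at 7 h. Of these 0 rose and 9 fell, or 1 and 14 adjusted over the list alone. The glycogen synthase gene GSY2 fell (-2.48 ± 0.31 at 11 h), HSP104 missed the threshold (adjusted p = 0.0502), and HSP26 measured -3.39 at 2 h. Proteasome genes (32) had a median of 0.91 at 5 h and -0.32 at 11 h. The trend test called 1 rising and 1 falling, or 3 and 4 adjusted over the list alone. RPN8 rose by 2.09 ± 0.23 at 5 h, and RPT2 measured 1.52 at 5 h. Vacuolar protease and autophagy genes (21) had a median of 0.78 at 0.5 h, with 2 rising and 3 falling, or 4 and 4 adjusted over the list alone. ATG1 measured 3.40 at 11 h without passing. On the fitted curve APE1 fell (-2.06 ± 0.48 at 11 h), though it measured 1.332 at 0.5 h before -1.336 at 11 h.

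Lists standing for other cell states were compared in the same way. Haploid and mating genes (17) had a median of 0.49 at 7 h, and 3 rose and 0 fell, with equal counts adjusted over the list alone. STE5 rose by 2.40 ± 0.21 at 9 h and AGA2 measured 2.30 at 7 h. Genes of vegetative G1 and budding (19) had a median of -0.48 at 11 h, and 0 rose and 4 fell, with equal counts adjusted over the list alone. ASH1 fell (-2.20 ± 0.26 at 9 h), while CLN3 measured -2.21 at 11 h without passing. Genes often used as references (10) had a median of 0.47 at 7 h, or 0.23 with the time zero array subtracted, with 2 rising and 1 falling, or 2 and 2 adjusted over the list alone. ALG9 rose by 2.38 ± 0.57 at 11 h, and TDH3 measured -2.73 at 7 h.

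No list passed fry in one direction after adjustment over the 69 tests, where 13 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0685. That value was shared by spore wall and late genes, middle genes and division genes for the change to 11 h, by early recombination genes for the change to 5 h, and by DNA replication genes for the changes to 2 and 5 h. The fitted change and the median at that time differed in sign in 15 of the 69 tests, ribosomal proteins at 11 h among them, and 0 of these 15 had an unadjusted p under 0.05.

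Early recombination and middle genes had positive medians at 2, 5, 7, 9 and 11 h under the converted naming, with -3.83 and -4.41 at 7 h if the sign is turned on all arrays. These lists hold genes known from sporulation time courses and the naming was inferred after the data had been seen, so their sign is not independent evidence, and the direction of the ratio stays likely only. The later arrays correlated with each other across genes at r from 0.319 to 0.936, and with the time zero array at r from -0.108 to 0.0212, where genes are not independent replicates.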

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

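All tests of explanations in this part were chosen after the results they explain had been seen, apart from the random orders of the times, which were planned but whose criterion was written afterwards. For the simpler spline, the outcomes that would count for or against were written down before it was run. Probes with no gene name entered no comparison above, and on the time zero array 2 of them were at least 2-fold higher and 0 lower. At the later times from 0.5 to 11 h, 30, 29, 42, 88, 78 and 70 of these probes were at least 2-fold higher, and 63, 42, 51, 82, 48 and 52 were at least 2-fold lower. Each count exceeds that of the time zero array. As shares of the unnamed probes with a value, 3.41 to 10.5% were higher and 4.94 to 9.75% lower, below the shares of named genes at every later time (7.81 to 15.6% and 7.83 to 17.3%).

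The 700 genes with a trend were set against 100 random orders of the times over the arrays. Of 101 orders, the real one included, 1 gave as many genes, and the highest of the others gave 316. The real order thus called more genes than any of the 100 drawn, which does not show that any single gene changed. An order without meaning still called up to 316 genes at an adjusted p under 0.05. Random orders can also separate neighbouring arrays that resemble each other (r = 0.936 for 7 and 9 h), whatever the cause of that likeness.

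No gene passed without the 2 h or without the 5 h array, and 43, 109 and 81 passed without the 7, 9 or 11 h array, each fit having 2 residual degrees of freedom in place of 3. Without the 0 h or the 0.5 h array, with as few, 1762 and 1363 genes passed, but the median residual SD there was 0.196 and 0.198 against 0.272 on 7 arrays and 0.274 to 0.292 in the 5 fits that called fewer genes, so these fits do not isolate the loss. A simpler spline of 2 degrees of freedom called 65.5% as many genes as its 1094 on 7 arrays without the 2 h array and 59% as many without the 5 h array, with 694 and 635 genes shared. It also went from 4 to 3 residual degrees of freedom, so these shares still hold the loss they were meant to remove and decide nothing. The loss of residual degrees of freedom may account for the drop, and it cannot be told apart from a dependence on the shape of the curve because both change with each array left out.

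The ribosomal protein genes had a median of -1.85 at 7 h under the converted naming and 0.011 by row number. That naming was chosen partly on the scatter of these probes at 7 h, so their place among other genes there (92.1% of 114 below the lower quartile of all other genes, -0.66) decides nothing. If the naming holds, centring each array on its median left the median of these genes at -1.74. It took the genes at least 2-fold lower at 7 h from 868 to 735. The median of all genes lay at -0.11 at 7 h, so this step could move the list no further. It shows that the choice of mean or median matters little for these genes, and cannot decide on centring as a cause. Their median on the time zero array was 0.205, and subtracting that array gave -2.02. This argues against a dye or spot bias that the time zero array shares. A bias of the 7 h array alone would not show there and stays open. A shift shared by all genes, which no centring shows, stays open, and no biological explanation was tested.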

How the results depend on the processing

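Naming by row number, centring per print tip, the list test in either direction and the spline of 2 degrees of freedom on 6 arrays were chosen after seeing the data. Counts of 2-fold genes stayed within 1.5 times under median centring, subtraction of the time zero array, no filter, other handling of repeat probes and print tip centring. Outside the central 99% range of the time zero array, 878, 814, 963 and 1176 genes were higher at 0.5, 2, 5 and 7 h, and 955, 905, 1086, 1509, 1406 and 1316 were lower from 0.5 to 11 h. Rising trend calls became 125 under quantile normalization and 978 with the time zero array subtracted and the curve also held at 0 at 0 h, a pair of choices that were changed together and not separated. Falling calls became 53 under quantile normalization and 988 under that pair, 575 with a spline of 2 degrees of freedom, 531 over ranks of time and 479 with a straight line. Leaving out single arrays gave 0 to 848 rising and 0 to 914 falling genes. The highest counts came without the 0 h array, where the change was counted from 0.5 h. Calls shared with the 700 were 159 under quantile normalization, 688 under that pair and 79 by row number. That naming puts the names on partly other probes (5017 genes with all values) and called 336 rising and 243 falling genes. All 40 named genes that passed lost the call without the 2 h and without the 5 h array. Of these, 37, 24 and 27 lost it without the 7, 9 or 11 h array. Quantile normalization took it from 19, a straight line from 10, and each other planned setting from at most 3. List tests passed went from 0 to 10 under that pair, to 6 by row number, to 33 in either direction, and from 0 to 4 when single arrays were left out (3 without the 5 h array, 4 without the 9 h array). With the time zero array subtracted alone, medians moved for core histones at 0.5 h (-1.15 to -1.48), glycolysis at 7 h (-2.78 to -3.06) and reference genes at 7 h (0.47 to 0.23). By row number the medians of 22 of the 23 lists moved by more than the SD of the time zero array or changed sign, most to near 0. Sign changed for 11, namely early recombination (3.83 to -0.016) and ribosomal proteins (-1.85 to 0.011) at 7 h, middle genes at 11 h (4.88 to -0.18), regulators of meiosis (0.84 to -0.383) and spore wall genes (3.88 to -0.481) at 9 h, DNA replication at 2 h (1.18 to -0.058), proteasome at 5 h (0.91 to -0.018), mitochondrial ribosome (-0.60 to 0.0225), vacuolar (0.78 to -0.15) and TCA cycle genes (0.74 to -0.272) at 0.5 h, and haploid genes at 7 h (0.49 to -0.078). Trends changed sign for SPS1 (adjusted p = 0.0391) and ATP2 (0.048). With the sign turned on all arrays, early recombination and middle genes had medians of -3.83 and -4.41 at 7 h. The cause of these shifts was not tested, except as stated for the arrays left out. No paired analysis was possible because each time point has 1 array. No signal over background was used here, so its limit on weak spots is unknown.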

Other observations

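Counting when a gene first reached 2-fold, chosen after seeing the data, 429 genes first stood higher at 0.5 h, 201 at 2 h, 268 at 5 h, 257 at 7 h, 49 at 9 h and 41 at 11 h. For lower genes the numbers were 523, 127, 200, 280, 101 and 72. At least 2-fold higher at all 6 later times were 76 genes, and lower at all 6 were 73. Another 78 genes were at least 2-fold higher at one time and lower at another.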
